A study of Homo sapiens with 6 samples.

How the data were processed

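Gene expression was measured on 6 Affymetrix arrays, of the HG-U133 Plus 2.0 design per the platform named in the annotation table, in Caco-2 cells at 0, 1, 3, 6, 24 and 48 h of coculture with THP-1 cells. Per the labels' protocols, total RNA was extracted with ISOGEN, purified on RNeasy columns, and 4 µg of it was made into biotin-labelled cRNA. The deposited values are intensities on a linear scale, as MAS5 signals per probe set; MAS5 is named in the submitters' processing notes, and its version, the scaling target and the detection calls are not given in the sources used here. MAS5 corrects background, sets perfect-match against mismatch probes and scales each array by a trimmed mean, so low signals are noisy and total RNA per cell is not measured. The 2% trimmed mean of the deposited intensities was 93.8 on each of the 6 arrays, and no further scaling was applied.

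Signals under 16.2, the 50th percentile of all values pooled over the arrays, were set to that floor, and log2 was taken. Of 54675 probe sets, 41097 carried 1 gene symbol in the annotation table, 1801 carried several and 11777 carried none. The 62 control probe sets of the manufacturer and all probe sets without exactly 1 symbol were left out of gene-level results. The gene identifiers of 41043 of the 41097 probe sets were found in a RefSeq gene table of assembly GRCh38.p14, which was used to update symbols and to give gene lengths (genomic span). For each of the 19775 genes the probe set with the highest mean log2 signal was used, and 10523 genes had at least 2 probe sets. At least 1 array was above the floor for 14623 genes, called measured genes here, and all 6 arrays were above it for 10446 genes. No column of the value table was left unused.

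Each coculture time was set against the single 0 h array. A gene counted as higher or lower when it differed at least 2-fold and the brighter of both arrays was above the floor; where the dimmer was at the floor, the fold is a lower bound. There is 1 array per time and no replicate, so no test was made, no p-value is given, and the number of arrays limits the precision. All values have n = 1, and the design holds no time-matched array of Caco-2 cells kept without THP-1 cells among those analysed here. Genes were also classed by time course. Early transient genes changed at least 2-fold at 1, 3 or 6 h and under 1.5-fold at both 24 and 48 h. Early sustained genes changed at least 2-fold in both periods, late genes only at 24 or 48 h, and the remainder were called intermediate.

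For 33 gene lists fixed before the data were examined, with 940 entries, the median log2 ratio over measured members was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression. A list is called apart from the random lists outside the percentiles 2.5 to 97.5, which 8.25 of the 165 pairs of list and time would do by chance. No probe set with a symbol of its own was found for 84 entries. Percentiles describe these arrays and are no test of the conditions.

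Measurement noise was estimated from the spread of log2 ratios between probe sets of the same gene at 0 and 1 h, in 9 bins of signal. Its robust SD was 0.64 at signals of 16 to 32, 0.41 at 64 to 128 and 0.15 above 1024. Arrays of unchanged genes with this noise and a shared 0 h array were simulated 100 times, and the mean counts of genes past 2-fold are given beside the observed counts. The spread between probe sets of a gene also holds real differences between transcripts, which can make the simulated noise too large. It leaves out the variation between cultures.

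On simulated arrays with 200 changed genes, drawn among those with a signal above 100 at 0 h, the size rule at each coculture time found 100% and 99.6% of genes changed by -2 and 2 on the log2 scale, and 96.4% and 92% of those changed by -1.5 and 1.5. It also called 3.31% of the unchanged genes among the 19775 genes of that simulation. These include genes under the floor, which cannot be called, so the share among measured genes is higher.

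The genes named in the text follow a rule fixed along with the lists. At each time these are the 10 largest rises and the 10 largest falls, among measured genes changed at least 1.5-fold the same way at a neighbouring time or in another probe set. Up to 4 members of each list with the largest changes were added, and 17 genes were always named. The rule gave 192 genes, part of which the text prints. Of 103 pairs of gene and time with at least 2 probe sets above the floor, the probe sets moved the same way in 85. Genes named outside the rule are said to have been chosen after their values were seen.

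The alternatives tried were quantile normalization, a common median of expressed probe sets, floors at the 30th and 65th percentiles (6.38 and 37.5), and the floor value as a pseudocount in place of the floor. Others were the median over a gene's probe sets, leaving out probe sets with the suffixes _x_at and _s_at, the 1 h array as the baseline, size rules of 1.5-fold and 3-fold, support by a neighbouring time or another probe set, and leaving out the 24 h or the 48 h array. A rule that the brighter of both arrays reach a signal of 100 was added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.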

Results

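Caco-2 is a human colorectal adenocarcinoma line whose cells form a polarised monolayer with features of small-intestinal enterocytes. THP-1 is a human monocytic leukaemia line that phorbol myristate acetate (PMA) turns into adherent macrophage-like cells. Caco-2 cells grown for 14 days on a porous membrane were set above THP-1 cells treated with PMA for 4 days in plates with 12 wells. The question was how Caco-2 gene expression changes during this coculture. RNA of the Caco-2 cells was profiled at 0, 1, 3, 6, 24 and 48 h, with 1 array at each time and no replicate.

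The arrays were alike in overall signal, with medians of 15.3 to 16.7 and 12006 to 12280 genes above the floor. The ratio of the 3' to the 5' control probe set of ACTB, a marker of RNA integrity and labelling, was not constant. It was 51.2 at 0 h, 27.7 at 1 h, 22.9 at 3 h, 18.0 at 6 h, 27.9 at 24 h and 37.0 at 48 h. The same ratio for GAPDH ranged from 3.54 at 6 h to 4.72 at 24 h. Spiked hybridisation controls were higher than at 0 h by a median log2 ratio of 0.28 at 24 h and 0.18 at 48 h. The median log2 ratio to 0 h over genes above the floor on all arrays lay between -0.04 at 1 h and -0.14 at 6 h.

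At 1 h, chemokine genes and feedback genes of the NF-kB pathway led the genes that rose, and by 6 h more genes had fallen than risen. Relative to 0 h, 278 genes were at least 2-fold higher at 1 h, 454 at 3 h, 619 at 6 h, 577 at 24 h and 559 at 48 h. At least 2-fold lower were 211, 514, 943, 898 and 898 genes in the same order. Simulated unchanged genes gave means of 321 to 324 in each direction, and the counts at 1 h lie below these. Observed counts hold noise as well as any change, so the simulated noise was too large for that array. The simulation thus cannot show whether the genes called at 1 h changed. Among genes whose brighter array reached a signal of 100, a restriction chosen after seeing the data, 150, 289, 414, 349 and 374 genes were higher and 55, 237, 525, 522 and 536 lower. The simulated means were then 43.9 to 46.0, with a highest single draw of 67. The 55 genes lower at 1 h lie inside that range.

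**Figure D1:**
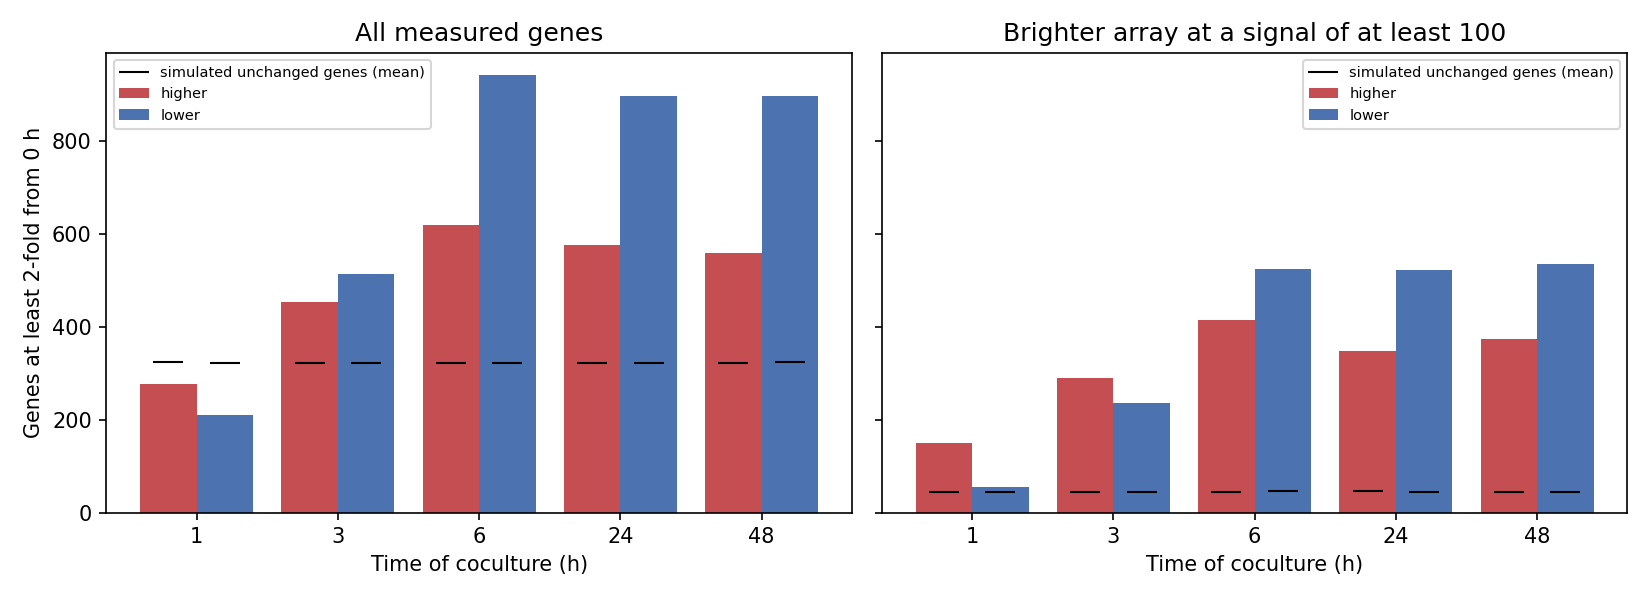
Number of genes at least 2-fold higher (red) or lower (blue) than at 0 h at each time of coculture, with 1 array per time; black marks give the mean count for simulated unchanged genes. Over all measured genes the counts at 1 h (278 and 211) lie below the marks, while among genes with a signal of at least 100 the higher counts (150 to 414) lie above them at each time.

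Chemokine genes, which encode secreted attractants of leukocytes, rose from 1 h. CXCL8, a neutrophil attractant, had a signal of 8.50 at 0 h, under the floor, and was at least 40.2-fold higher at 1 h, 57.0-fold at 3 h and 94.9-fold at 6 h, where its signal was 1541. At 48 h its signal was 36.0. CXCL1 rose 41.6-fold at 1 h, and CXCL3 12.1-fold, both also neutrophil attractants. CCL20, which attracts cells bearing CCR6, rose 9.50-fold at 1 h and was still 9.33-fold higher at 24 h. CXCL10, a T cell attractant often induced by interferon, was at least 15.7-fold higher at 6 h. Of the 12 measured chemokine genes, 6 were higher at 1, 3 and 6 h, 5 at 24 h and 3 at 48 h, and none was lower. Their median log2 ratio was 1.54, 1.78, 1.71, 0.68 and 0.24 at 1, 3, 6, 24 and 48 h, apart from the random lists at each time. Only 6 of the 12 were above the floor at 0 h and 6 never passed the size rule, so the median depends on the processing. It was 0 at 1 h, within the random lists, without probe sets ending in _x_at and _s_at and 0.18 with the median over a gene's probe sets. At 48 h it lay within the random lists with the floors at the 30th (0.12) and 65th (0.03) percentiles. With the 1 h array as the baseline the medians at 3 and 24 h were 0.05 and -0.10, within the random lists, that at 6 h was 0.16, near their upper edge, and that at 48 h was -0.97, below them. Log2 ratios of the probe sets of CXCL8 at 6 h ran from 0.32 to 6.57.

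Genes of the NF-kB pathway, a list of its inhibitors, its subunits and other target genes, rose as a group from 1 h. TNFAIP3, an inhibitor of NF-kB signalling, was 9.48-fold higher at 1 h and 9.57-fold at 6 h. IER3 was 9.91-fold higher at 1 h, RELB 7.52-fold at 3 h and NFKB2 6.70-fold at 6 h. NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, was 4.73-fold higher at 3 h and had a log2 ratio of -0.43 at 48 h. ICAM1, an adhesion molecule for leukocytes, was 4.66-fold higher at 6 h. Of 24 measured members, 12, 15, 15, 14 and 4 were higher at 1, 3, 6, 24 and 48 h, and none was lower at any time. The median log2 ratio was 0.93, 1.20, 1.46, 1.07 and 0.31, above the random lists at each time. Without probe sets ending in _x_at and _s_at the median was 0.36 at 1 h, 0.92 at 6 h and 0.17 at 48 h, the last within the random lists. Against the 1 h array instead of 0 h, the medians were 0.18, 0.40, -0.0082 and -0.35 at 3, 6, 24 and 48 h, that at 24 h within and that at 48 h below the random lists.

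Immediate early genes, which encode transcription factors and phosphatases made soon after a stimulus, had 16, 15, 17, 12 and 7 of 33 members higher. NR4A1 was 9.64-fold higher at 1 h, with log2 ratios of 0.98 to 3.27 over its probe sets. EGR1 was 6.92-fold and JUNB 6.19-fold higher at 1 h, and ZFP36, which promotes decay of cytokine mRNA, 7.05-fold at 6 h. The list medians were 0.99, 0.89, 1.02, 0.80 and 0.49. The list of EGF receptor ligands and signalling genes, which also holds receptors, had 5, 8, 8, 5 and 6 of 15 members higher, with medians of 0.45, 1.35, 1.04, 0.52 and 0.66. EPHA2, a receptor tyrosine kinase, was 8.95-fold, PHLDA1 7.59-fold and SPRED1, an inhibitor of the Ras pathway, 4.15-fold higher at 6 h. Genes of matrix remodelling and wound repair had 8 of 23 members higher at 6 h and 7 at 24 h, with medians of 0.64 and 0.68 and none lower. MMP1, an interstitial collagenase, was 10.7-fold, PLAUR, the urokinase receptor, 8.0-fold and the integrin ITGA2 6.35-fold higher at 6 h. All 3 lists lay above the random lists at each time, but without _x_at and _s_at probe sets the immediate early median at 48 h (0.14) and the matrix median at 1 h (0.11) lay within them. Against the 1 h array the immediate early medians lay within the random lists at 3 and 6 h (-0.0091 and 0.04) and below them at 24 and 48 h (-0.22 and -0.43). On that baseline the EGF receptor medians at 3, 24 and 48 h (0.07, 0.24 and -0.09) and the matrix median at 48 h (0.00) lay within them. The ACTB 3' to 5' ratio was lower at each coculture time (18.0 to 37.0) than at 0 h (51.2). A difference in RNA integrity or labelling was not tested for these 3 lists.

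Of the cytokine genes, LTB was at least 8.77-fold higher at 6 h, EBI3 4.56-fold at 24 h and IL1B 2.99-fold at 6 h, while TNFSF10, the death ligand TRAIL, was 10.4-fold lower at 24 h. TNF stayed under the floor at each time, with a signal of 1.22 at 0 h, and IL6 rose above it only at 1 h, with a signal of 22.9. Of 18 measured cytokine genes 5 were higher at 24 h and 1 lower, and the median log2 ratio was 0.03 at 1 h and 0.28 to 0.45 later. With the median over a gene's probe sets it was 0.11, 0.09 and 0.06 at 3, 24 and 48 h, within the random lists, without _x_at and _s_at probe sets it was 0.00 at 6 h, and against the 1 h array 0.07 at 48 h, these also within them. Receptors of innate signals had 5 of 22 members higher at 3 h and none lower, with medians of 0.24 and 0.39 at 3 and 6 h, the former 0.05 and within the random lists with the median over a gene's probe sets. Examples are IRAK2, a kinase of interleukin-1 signalling, 5.30-fold higher at 6 h, and TNFRSF1A, a receptor of TNF, 3.06-fold higher at 3 h. The JAK-STAT list had 5 of 25 members higher at 3 and at 6 h, with PIM3 3.73-fold higher at 1 h and IL4R 2.63-fold at 6 h, and a median of 0.38 at 6 h.

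**Figure D2:**
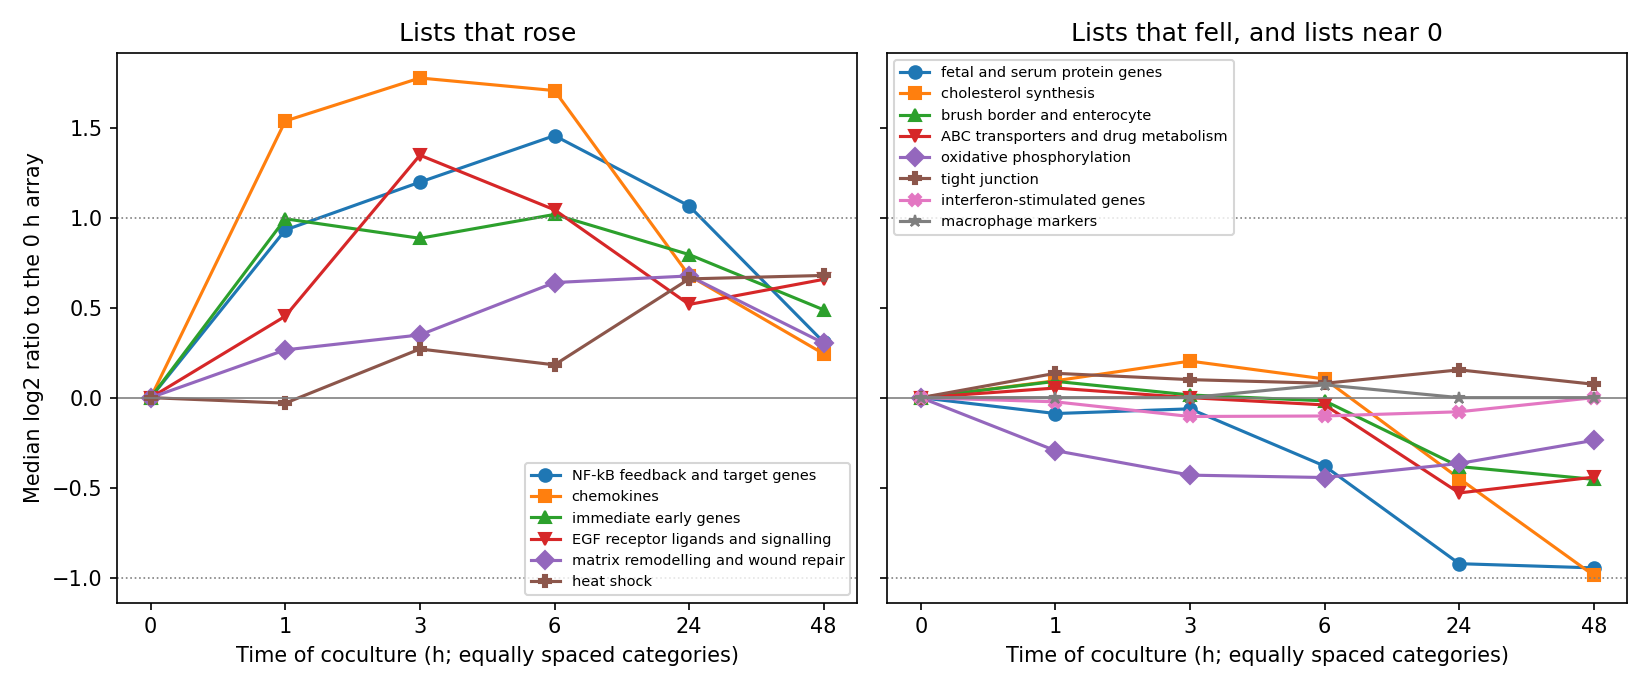
Median log2 ratio to the 0 h array over the measured members of 14 gene lists (y axis) against time of coculture in h (x axis, equally spaced categories), with 1 array per time; dotted lines mark 2-fold. The NF-kB list reaches 1.46 and the chemokine list 1.71 at 6 h, while the serum protein list falls to -0.95 and the cholesterol synthesis list to -0.99 at 48 h.

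Among single genes outside these lists, ITGB8, an integrin subunit that binds latent TGF-beta, was 20.1-fold higher at 6 h and 12.4-fold at 48 h, though log2 ratios of its probe sets at 6 h ran from 0.76 to 4.33. DHRS9, a retinol dehydrogenase, was 11.7-fold higher at 6 h and had a log2 ratio of -0.30 at 48 h. ARL14 was 8.56-fold higher at 1 h. PMEPA1, an inhibitor of TGF-beta signalling, had log2 ratios of 3.19 at 6 h and 2.69 at 24 h. TCIM was at least 23.1-fold higher at 3 h, and at 48 h it was under the floor. Late rises included CASP5, an inflammatory caspase, 10.6-fold higher at 48 h, and PGF, a growth factor of the VEGF family, 5.60-fold at 48 h. Log2 ratios of the 2 probe sets of PGF were 0.64 and 2.48.

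The genes with the largest falls at 3 and 6 h were of varied function. MRPL34, a protein of the mitochondrial ribosome, was 7.40-fold lower at 3 h and 13.8-fold at 6 h. ID1, an inhibitor of basic helix-loop-helix factors, was higher at 1 h by a log2 ratio of 1.36 and then 10.4-fold lower at 6 h and 12.9-fold at 48 h. MVB12A was 7.11-fold, MPG, a DNA glycosylase, 8.59-fold and NAPA 6.02-fold lower at 6 h. TXNIP, which binds thioredoxin, was 4.92-fold lower at 3 h and 11.5-fold at 48 h, with log2 ratios of 0.15 to -2.30 over its probe sets at 3 h. At 1 h the largest falls with support at a neighbouring time or in another probe set were those of FAM13A-AS1, 9.03-fold, and HILPDA, a lipid droplet protein, 4.20-fold. The cell cycle list had 6 of 38 members lower at 6 h and 5 at 24 h, with medians of -0.44 and -0.42, the latter -0.27 and within the random lists without _x_at and _s_at probe sets, and MCM5, a replication helicase subunit, was 5.01-fold lower at 6 h. The oxidative phosphorylation list had medians of -0.29, -0.43, -0.44, -0.37 and -0.24, below the random lists at each time, with 5 of 31 members lower at 6 h. It lay within the random lists at 48 h without _x_at and _s_at probe sets (-0.25), and against the 1 h array at 6, 24 and 48 h (-0.15, -0.07 and 0.07). NDUFS3, a subunit of complex I, was 3.89-fold and ATP5MC1, a subunit of the ATP synthase, 2.79-fold lower at 6 h. The ACTB 3' to 5' ratio was highest at 0 h (51.2) and lowest at 6 h (18.0), the time at which both list medians were lowest.

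At 24 and 48 h, genes of liver-type secreted proteins, of cholesterol synthesis and of absorptive enterocytes fell. Serum protein genes, which Caco-2 cells share with hepatocytes, had 8 of 24 members lower at 24 h and 10 at 48 h, with medians of -0.92 and -0.95 and none higher. Their median was already below the random lists at 6 h (-0.38, and -0.23 against the 1 h array). TF, which encodes transferrin, was 7.42-fold, the fibrinogen chain FGB 6.53-fold and SERPINC1, antithrombin, 5.08-fold lower at 48 h. Log2 ratios of the probe sets of TF at 48 h ran from -2.89 to -0.16, the weakest being near the floor. Cholesterol synthesis genes had 4 of 19 members lower at 24 h and 9 at 48 h, with medians of -0.45 and -0.99, after a median of 0.20 at 3 h that lay above the random lists (0.09 against the 1 h array, within them). At 6 h it was 0.10 and within them, but 0.34 to 0.36 and above them with the floor at the 30th percentile, with a pseudocount or without _x_at and _s_at probe sets. TM7SF2, a sterol reductase, was 3.89-fold and ACAT2, an acetoacetyl-CoA thiolase, 2.51-fold lower at 24 h, and LSS, which makes lanosterol, 2.64-fold at 48 h. IDI1 was 2.74-fold lower at 48 h, but its log2 ratios ran from -1.46 to 0.82 over its probe sets.

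Brush border and enterocyte genes had 6 of 34 members lower at 24 h and 9 at 48 h, with medians of -0.38 and -0.45, both below the random lists, while 3 members were higher at 24 h. The median at 24 h was -0.17 with the median over a gene's probe sets, and that at 48 h was -0.25 without _x_at and _s_at probe sets, both within the random lists. At 1 h it was 0.09 and within them. It lay above them there under quantile normalization (0.12), a common median (0.08) and the median over a gene's probe sets (0.21). The disaccharidases SI and LCT were 4.50-fold and 4.30-fold lower at 48 h, and FABP1, a fatty acid carrier, 4.37-fold. In contrast, KRT20, a keratin of differentiated enterocytes, was 4.04-fold higher at 24 h. VIL1, the actin bundler of microvilli, had a log2 ratio of -0.63 at 48 h and ALPI, intestinal alkaline phosphatase, -0.82 at 24 h, neither past 2-fold. With falls to the floor counted at their lower bound, the largest fall of any gene was that of S100G, the vitamin D-dependent calcium carrier of enterocytes. Its signal went from 1699 at 0 h to 39.8 at 48 h, 42.7-fold lower. SLC10A2, the ileal bile acid transporter, was 11.6-fold, SLC39A4, a zinc transporter, 4.61-fold and the fructose transporter SLC2A5 3.57-fold lower at 48 h. The list of nutrient and ion transporters had 7 of 33 members lower at 48 h, but its median of -0.19 lay within the random lists (-0.28 against the 1 h array, below them). At 6 h its median of -0.11 lay within them, but with the median over a gene's probe sets it was 0.31 and above them. SLC15A1, a peptide transporter, and SLC6A6, the taurine transporter, had log2 ratios of 0.32 at 1 h and -0.51 at 6 h at most.

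Genes of ABC transporters and drug metabolism had 7 of 29 members lower at 24 h and 9 at 48 h, with medians of -0.53 and -0.44, which were -0.02 and -0.17 and within the random lists without _x_at and _s_at probe sets. UGT2B17, a glucuronosyltransferase, was at least 17.2-fold and GSTA1, a glutathione transferase, 9.28-fold lower at 48 h. Both belong to families of near-identical paralogs that probe sets may not separate. ABCB1, the efflux pump P-glycoprotein, was 2.06-fold higher at 24 h. FMO1 and ADH4, further oxidising enzymes, were 9.37-fold and 9.32-fold lower at 48 h. Acute phase and mucosal defence genes had 8 of 25 members lower and 1 higher at 48 h, with a median of -0.40, below the random lists at that time alone, though at 24 h the median against the 1 h array (-0.22) was at their lower edge. FGA and FGG, the other fibrinogen chains, were 6.99-fold and 4.92-fold lower at 48 h, and ORM1, orosomucoid, 3.45-fold. These 3 are liver-type plasma proteins like those of the serum protein list.

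**Figure D3:**
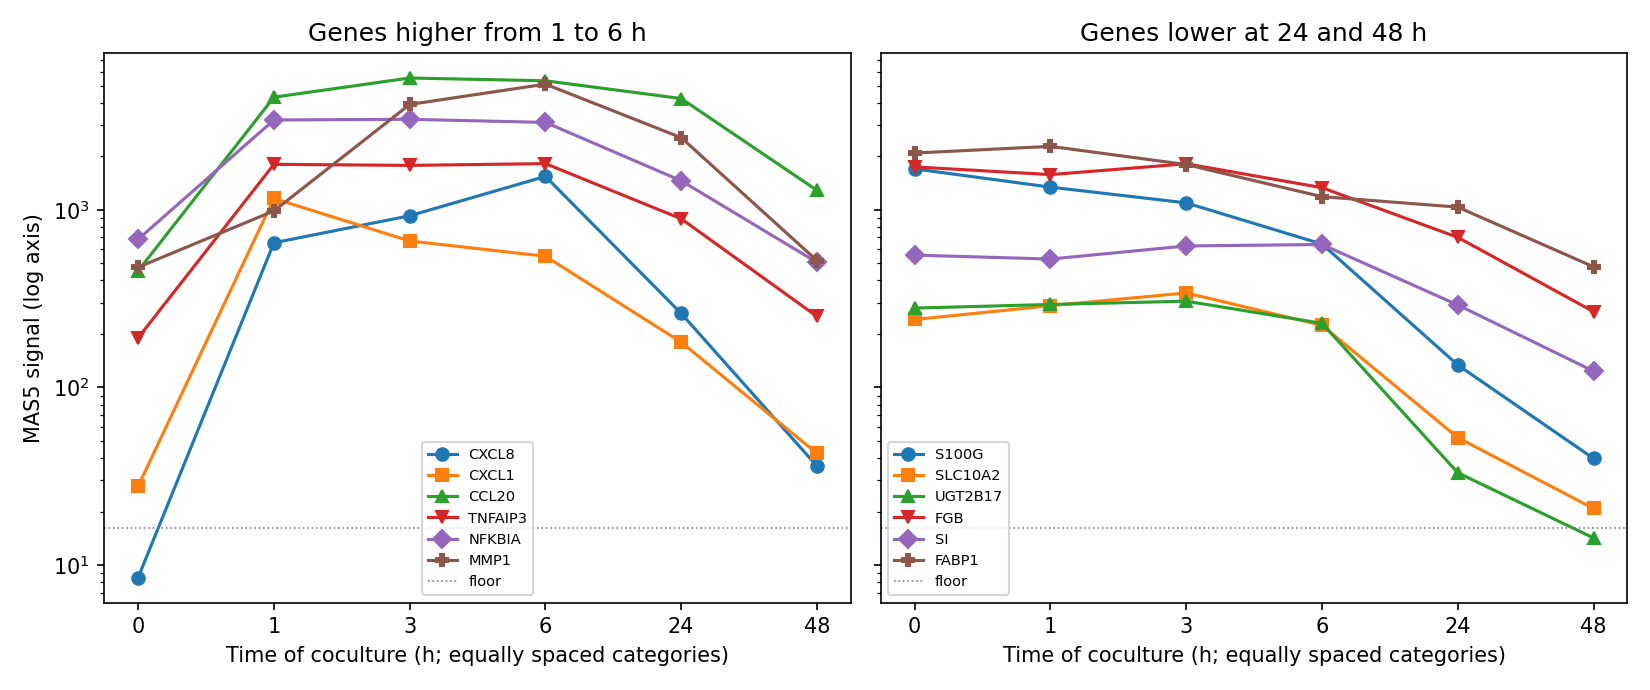
MAS5 signal (log axis) of 6 genes that were higher from 1 to 6 h (left) and 6 that were lower at 24 and 48 h (right) against time of coculture in h (equally spaced categories), with 1 array per point; the dotted line is the floor of 16.2. CXCL8 goes from 8.50 at 0 h to 1541 at 6 h and 36.0 at 48 h, and S100G from 1699 to 39.8.

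Stress-related lists moved at different times. Heat shock genes had 4 of 16 members higher at both 24 and 48 h and 1 lower, with medians of 0.66 and 0.68. HSPA6, an inducible chaperone, was 12.4-fold higher at 24 h and HSPB1 5.32-fold lower at 6 h. The unfolded protein and integrated stress response list had a median of 0.57 at 48 h, with 4 of 28 members higher, among them DNAJB9 3.50-fold and the stress sensor ERN1 2.83-fold. Target genes of p53 had a median of 0.61 at 6 h with 5 of 16 higher, led by PLK2 at 4.84-fold, but a median of 0.17 without _x_at and _s_at probe sets. The cell death list had a median of 0.45 at 24 h with 5 of 27 higher (0.21 without those probe sets, and 0.14 and within the random lists against the 1 h array), and TNFRSF10A, a receptor of TRAIL, was 3.88-fold higher at 3 h. Hypoxia response genes had a median of -0.16 at 1 h and 0.38 at 6 h, where 4 of 23 were higher, but -0.11 and 0.18 without those probe sets, and ERO1A was 3.72-fold and the glucose transporter SLC2A1 2.86-fold higher at 24 h. These 4 medians without such probe sets lay within the random lists. At 48 h the hypoxia median was 0.04 and within them, but 0.41 and above them against the 1 h array. Counted over all times, 4 of the 23 hypoxia genes were higher and 5 lower, and HILPDA had a log2 ratio of -1.20 at 24 h. Medians of glycolysis genes lay between -0.22 and -0.05, below the random lists at 1 h, though within them there under 6 of the alternatives, and at 3 h only with a common median (-0.20) and the floor at the 65th percentile (-0.22), with ALDOC 3.06-fold lower at 48 h. The list of oxidative stress genes had medians of -0.17 to -0.03 within the random lists, except -0.19 at 1 h with the median over a gene's probe sets, with CAT, catalase, 4.12-fold lower and GPX2 3.25-fold higher at 24 h. Of 6 measured metallothioneins 2 were lower at 1 and 3 h, with MT1F at least 3.91-fold lower at 3 h and list medians of -0.15 to 0.00 within the random lists, except -0.60 at 6 h with a pseudocount in place of the floor.

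Few tight junction genes passed 2-fold. Of 22 measured members only PARD6B passed the size rule upward, 2.37-fold at 48 h, and only CRB3 downward, 2.41-fold at 24 h. TJP1, the scaffold protein ZO-1, had its largest log2 ratio of 0.92 at 6 h, CLDN1 0.53 and CLDN2 0.59 at 3 h, and OCLN -0.19 at 24 h. The list medians lay between 0.07 and 0.15, above the random lists at 1 h (percentile 97.8) and within them later. With the median over a gene's probe sets they were 0.33 at 24 h and 0.22 at 48 h, above the random lists, as was 0.24 at 24 h with the floor at the 30th percentile. At 1 h the median lay within the random lists under 4 alternatives. Adherens junction and desmosome genes had medians of 0.19 to 0.48, above the random lists at 1, 24 and 48 h, with NECTIN2 2.38-fold higher at 3 h. Relative to the 1 h array they were 0.20 at 24 h, within the random lists, and 0.23 at 48 h, at their edge (percentile 97.6). At 3 and 6 h they lay above the random lists with the floor at the 65th percentile and with the median over a gene's probe sets. Probe sets of OCLN gave log2 ratios of -0.62 to 1.19 at 24 h, and single values of these genes therefore depend on the probe set.

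Interferon-stimulated genes did not move as a group, with medians of -0.10 to 0.00 within the random lists at each time. Of 33 members, 3 were higher and 3 lower at 6 h. ISG20 was 2.97-fold higher at 6 h, and IFIT1 was 5.52-fold and BST2 2.70-fold lower at 24 h. Antigen presentation genes had medians of -0.02 to 0.15 within the random lists and no member higher. They lay above the random lists at 24 h under quantile normalization (0.18), a common median (0.20) and the median over a gene's probe sets (0.19), and at 6 h with the floor at the 65th percentile (0.23). PSME1, a proteasome activator, was 2.62-fold lower at 6 h. Fatty acid oxidation genes had medians of -0.26 to 0.00 within the random lists, but at 24 h lay below them under 5 alternatives (-0.37 to -0.23), with ACSL5 2.65-fold higher at 6 h and ECI2 2.65-fold lower at 48 h. Genes of goblet, Paneth and enteroendocrine cells had medians of -0.05 to 0.04 (at 48 h -0.29 without _x_at and _s_at probe sets and -0.22 against the 1 h array, below the random lists) and went both ways, MUC13 3.17-fold higher at 6 h and TFF3 3.52-fold lower at 48 h. Stem cell and Wnt target genes had medians of 0.24 and 0.30 at 6 and 24 h, with 2 of 18 higher at 24 h, but 0.11 and 0.02, within the random lists, with the median over a gene's probe sets. Ribosomal protein genes, a control list, had medians of -0.11 to 0.02, below the random lists at 1 h (-0.10, but -0.03 and within them under quantile normalization) and, without _x_at and _s_at probe sets, at 3 h (-0.20), with RPS25 2.49-fold lower at 3 h.

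Markers of macrophages were followed because THP-1 cells shared the wells. The list medians were 0.00 at 1, 3, 24 and 48 h and 0.07 at 6 h, the last at percentile 98.3 of the random lists, but 0.00 with the median over a gene's probe sets or without _x_at and _s_at probe sets. It was larger, and still above the random lists, with the floors at the 30th (0.19) and 65th (0.16) percentiles, with a pseudocount (0.22) and against the 1 h array (0.15). Of the 25 measured members only 10 were above the floor on all arrays, so a median of 0.00 says little. PTPRC and SPI1, found in leukocytes, stayed under the floor on each array. TYROBP, chosen for printing after its values were seen, had signals of 14.0 at 0 h, 11.5 at 1 h, 1.71 at 3 h, 19.3 at 6 h, 11.7 at 24 h and 25.5 at 48 h. MMP9, a gelatinase, was 5.51-fold higher at 6 h and the secreted phosphoprotein SPP1 3.94-fold at 48 h, both of which epithelial cells can also express. AIF1 was 8.37-fold lower at 48 h and MSR1 3.69-fold lower at 24 h.

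By time course, 250 genes rose early and transiently, 357 rose early and stayed raised at 24 or 48 h, 483 rose late and 230 were intermediate. Among genes that fell, 266 were early transient, 614 early sustained, 661 late and 350 intermediate. Simulated unchanged genes sharing the 0 h array gave means of 561, 143, 466 and 169 for rises and of 96.3, 321, 127 and 114 for falls. Independent early and late calls would share 48.1 genes upward and 107 downward. With a signal of at least 100 on the brighter array, 173, 206, 313 and 117 genes rose against simulated means of 86.2, 15.1, 69.9 and 20. In the same order, 98, 313, 398 and 202 genes fell against 29.1, 33.0, 38.6 and 31.7. The single 0 h array could not be split, so part of the excess of sustained genes may come from it. At all 5 times 43 genes were higher and 26 lower, and 15 genes changed in opposite directions early and late.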

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

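All tests of explanations in this part were chosen after the results were seen, and those on macrophage RNA replaced tests on the macrophage list median, which can hardly move while many members lie at the floor. With 1 array per time, differences between times were not tested.

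ARL14, HILPDA and ID1, of the named genes, passed 2-fold in opposite directions at early and late times. The log2 ratio of ARL14 was 2.503 at 6 h and -1.13 at 48 h, that of HILPDA -2.07 at 1 h, 1.10 at 6 h and -1.20 at 24 h, and that of ID1 1.36 at 1 h and -3.69 at 48 h.

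Probe sets without a gene symbol took no part in the comparisons. Of 11721 such probe sets, 212, 296, 302, 284 and 305 were at least 2-fold higher and 145, 172, 269, 232 and 221 at least 2-fold lower at 1, 3, 6, 24 and 48 h, with 4380 to 4688 of them above the floor. Simulated unchanged probe sets gave means of 225 to 229 higher and 224 to 225 lower. The counts at 1 h, and those lower at 3, 24 and 48 h, do not exceed the highest simulated counts of 255 to 272. As for the named genes, the simulated noise may be too large. The control probe set at the 5' end of ACTB was 3.05-fold higher at 6 h than at 0 h.

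The rise of NF-kB and chemokine genes at 1 to 6 h could come from macrophage RNA in the harvest, a 0 h array that stands apart, a difference in RNA integrity, or handling. Macrophage RNA as the whole source at 1 and 3 h is argued against by 9 abundant macrophage transcripts, many of them near the floor: 0 were higher, and their summed signal changed by -0.0108% at 1 h and -0.145% at 3 h of the gain of the NF-kB and chemokine genes. At 6 h that share was 0.361% with 1 of 9 higher (SRGN), so a small amount of such RNA there cannot be told apart from expression in Caco-2 cells. Outside these 9, the macrophage marker SPP1 had log2 ratios of 1.29 at 1 h, -0.05 at 3 h and 1.80 at 6 h, and MMP9 2.46 at 6 h. Other members of the macrophage list fell, FCER1G by -1.13 at 1 h and AIF1 by -1.70 at 3 h and -1.23 at 6 h. The 0 h array alone is argued against by NF-kB medians of 0.35, 1.10 and 1.32 at 1, 3 and 6 h relative to the 48 h array, all above the random lists. The median at 1 h was smaller there than relative to 0 h (0.93). RNA integrity or labelling cannot be told apart, because the ACTB 3' to 5' ratio fell as the NF-kB median rose. The rank correlation over the 6 arrays, 1 per time, was -0.943. The GAPDH ratio followed the median less closely. It was 4.69 at 0 h, 3.54 at 6 h and 4.72 at 24 h, where the NF-kB median was 1.07. Handling cannot be told apart either, since 0 arrays after 0 h without THP-1 cells were analysed here. A response to THP-1 cells is an untested hypothesis.

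Serum protein, cholesterol synthesis and enterocyte genes fell at 24 and 48 h, the enterocyte list with the exceptions given above. Against the 1 h array all 3 lists stayed below the random lists at 48 h, the weakest median being -0.51. This argues against the 0 h array as the source. Against the 6 h array, whose ACTB 3' to 5' ratio lay farthest from that at 0 h, the weakest was -0.33. That argues against RNA integrity as far as this ratio shows it. A labelling or hybridisation difference of the late arrays is not covered. The hybridisation controls had median log2 ratios to 0 h of 0.28 at 24 h and 0.18 at 48 h, but 0.01 at 6 h. Dilution by THP-1 RNA as the whole cause would lower epithelial transcripts alike, but 41 junction genes had medians of 0.38 and 0.22 at 24 and 48 h, with lower bounds of 0.07 (2.5th percentile over resampled genes), against -0.38 and -0.45 for the weakest falling list. Time in culture without THP-1 cells may give the same fall and cannot be told apart from coculture, because 0 arrays after 0 h without THP-1 cells were analysed here. The response to coculture, which the design names, is therefore open as well.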

How the results depend on the processing

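The signal over background, and the single array per time, limit what these values can show: the floor of 16.2 is the 50th percentile of all values. Of the alternatives, quantile normalization and a common median kept every count, class and list named among the 7 primary lists within 1.5 times or within the list's random spread. Among the 75 pairs of list and time that lay outside the random lists, 75, 75, 75, 75, 75, 74 and 72 kept their direction under quantile normalization, a common median, the floors at the 30th and 65th percentiles, a pseudocount, the median over probe sets and without _x_at and _s_at probe sets. Still outside the random lists were 72, 73, 68, 68, 74, 64 and 52 of them in the same order. Against the 1 h array, 52 of 63 such pairs kept their direction and 39 stayed outside. Counting only genes backed at a neighbouring time or by another probe set left all 10 counts within 1.5 times. Over all alternatives, 71 counts, 56 classes, 201 medians of primary lists and 1340 values of named genes stayed within those bounds or the measurement noise, 384 values of named genes moved in size, and of the other lists 837 medians stayed and 161 moved. Of the values that left those bounds, the counts, the classes, the medians of the 7 primary lists and the values that changed sign follow. Apart from the size rules, the brightness rule and the arrays left out, which change what is counted, the cause was not tested.

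With the floor at the 30th percentile (6.38), 812, 1225, 1474, 1393 and 1246 genes were higher at 1, 3, 6, 24 and 48 h and 961, 1256, 1750, 1671 and 1644 genes were lower at 1, 3, 6, 24 and 48 h. At that floor there were 806 early transient, 1066 early sustained, 981 late and 520 intermediate genes that rose, and 608 early transient, 1476 early sustained and 568 intermediate genes that fell. Its list medians were 1.61 at 6 h for NF-kB genes, 0.23, 0.78 and 0.46 at 1, 3 and 6 h for chemokines, and -0.15, -0.35, -0.25 and -0.24 at 1, 6, 24 and 48 h for interferon-stimulated genes. Other medians were -0.36 at 6 h for acute phase genes, -0.70 at 48 h for brush border genes, and 0.19 at 6 h for macrophage markers.

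With the floor at the 65th percentile (37.5), 168 genes were higher at 1 h and 79, 290 and 609 genes were lower at 1, 3 and 6 h. That floor gave 157 early transient, 233 early sustained and 153 intermediate genes that rose, and 125 early transient, 367 early sustained and 232 intermediate genes that fell. Its list medians were 1.13 at 1 h for NF-kB genes, 2.75, 2.74, 2.79, 1.56 and 0.034 at 1, 3, 6, 24 and 48 h for chemokines, and -0.22 at 6 h for interferon-stimulated genes. Other medians were -0.36 and -0.32 at 6 and 24 h for acute phase genes, 0.030 at 1 h for brush border genes, and 0.16 and -0.15 at 6 and 48 h for macrophage markers.

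Under a 1.5-fold rule, 955, 1397, 1649, 1758 and 1634 genes were higher at 1, 3, 6, 24 and 48 h and 1179, 1990, 2800, 2508 and 2559 genes were lower at 1, 3, 6, 24 and 48 h.

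Under a 3-fold rule, 70, 127, 165, 107 and 105 genes were higher at 1, 3, 6, 24 and 48 h and 19, 55, 139, 196 and 197 genes were lower at 1, 3, 6, 24 and 48 h.

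Where the brighter array had to reach a signal of 100, an alternative chosen after seeing the data, 150, 289 and 349 genes were higher at 1, 3 and 24 h and 55, 237, 525, 522 and 536 genes were lower at 1, 3, 6, 24 and 48 h. This left 206 early sustained, 313 late and 117 intermediate genes that rose, and 98 early transient, 313 early sustained, 398 late and 202 intermediate genes that fell.

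Against the 1 h array, 197, 354 and 373 genes were higher at 3, 6 and 24 h and 191 and 467 genes were lower at 3 and 6 h. This baseline gave 164 early transient, 155 early sustained and 135 intermediate genes that rose, and 151 early transient, 290 early sustained and 141 intermediate genes that fell. Its list medians were 0.18 and 0.40 at 3 and 6 h for NF-kB genes, 0.046 and 0.16 at 3 and 6 h for chemokines, and 0 at 3 h for interferon-stimulated genes, 0.039 and -0.0067 at 3 and 6 h for acute phase genes. Other medians were -0.0054 at 24 h for tight junction genes, -0.53 at 24 h for brush border genes, and 0.15 at 6 h for macrophage markers. Medians that changed sign were -0.0082 and -0.35 at 24 and 48 h for NF-kB genes, -0.10 and -0.97 at 24 and 48 h for chemokines, -0.0091, -0.22 and -0.43 at 3, 24 and 48 h for immediate early genes. The others that changed sign were -0.14 at 48 h for pattern and TNF/IL-1 receptors, -0.085 at 48 h for EGF receptor ligands and signalling and 0.067 at 48 h for oxidative phosphorylation. Log2 ratios that changed sign were those of CXCL1 (-0.79 at 3 h), CXCL3 (-0.22 at 3 h), CXCL1 (-1.08 at 6 h), CXCL8 (-1.32 at 24 h), CCL20 (-0.025 at 24 h), CXCL10 (-0.24 at 24 h) and CXCL1 (-2.69 at 24 h).

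Without the 24 h array, there were 420 early transient and 219 early sustained genes that rose, and 442 early transient genes that fell.

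Without the 48 h array, there were 270 late genes that rose, and 401 late genes that fell.

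With a pseudocount in place of the floor, there were 384 early sustained genes that fell. Its list medians were 0.88 at 24 h for NF-kB genes, 1.45 and 0.49 at 1 and 48 h for chemokines, and -0.13, -0.20 and -0.084 at 1, 24 and 48 h for interferon-stimulated genes. Other medians were -0.33 at 6 h for acute phase genes, and -0.084 and 0.22 at 3 and 6 h for macrophage markers.

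With the median over a gene's probe sets, list medians were 0.72, 1.05 and 0.77 at 1, 6 and 24 h for NF-kB genes, 0.18, 0.53, 0.62 and 0.42 at 1, 3, 6 and 24 h for chemokines, and -0.29 at 48 h for acute phase genes. Other medians were 0.33 and 0.22 at 24 and 48 h for tight junction genes, 0.21, -0.17 and -0.33 at 1, 24 and 48 h for brush border genes, and 0 at 6 h for macrophage markers. Log2 ratios that changed sign were those of ZNF160 (-0.26 at 48 h), TAP2 (0.48 at 6 h) and CTNNB1 (-0.71 at 48 h).

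Without probe sets that can bind several transcripts (suffixes _x_at and _s_at), list medians were 0.36, 0.55, 0.92, 0.59 and 0.17 at 1, 3, 6, 24 and 48 h for NF-kB genes, 0, 0.43, 0.61 and 0.40 at 1, 3, 6 and 24 h for chemokines, and 0 at 1 h for acute phase genes. Other medians were -0.25 at 48 h for brush border genes, and 0 at 6 h for macrophage markers. Log2 ratios that changed sign were those of SIVA1 (0.064 at 1 h), IDI1 (0.13 at 48 h) and NDUFA2 (0.73 at 6 h).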

Other observations

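The gene families in this part were chosen after seeing which genes had moved, and the tests on them were chosen after the results were seen. In the TNF receptor superfamily, of 16 measured members, 10 were at least 2-fold higher at 3 h, 9 at 6 h and 7 at 24 h, and none was lower. The median log2 ratio was 1.22, 1.08 and 0.81 at 3, 6 and 24 h, but 0.62, 0.67 and 0.37 with the floor at the 65th percentile. Without _x_at and _s_at probe sets it was 0.72 at 6 h and 0.41 at 24 h. Against the 1 h array it was 0.60, 0.29 and 0.08 at 3, 6 and 24 h, the last within the random lists, with 3, 4 and 2 members higher. The ACTB 3' to 5' ratio was lower at these times (22.9, 18.0 and 27.9) than at 0 h (51.2). A difference in RNA integrity or labelling was not tested for this family. TNFRSF9, a costimulatory receptor, was 5.61-fold and TNFRSF11B, the decoy receptor osteoprotegerin, 4.91-fold higher at 6 h, and TNFRSF10B, another TRAIL receptor, 3.11-fold. The ligand TNFSF10 itself was 10.4-fold lower at 24 h.

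Enzymes of the UGT2 family, which conjugate steroids and drugs, fell late. Of 5 measured members 3 were lower at 24 and 48 h, with medians of -1.74 and -2.51. Without _x_at and _s_at probe sets these were -0.42 and -0.89, so the size of the medians depends on probe sets that may not separate the paralogs. The smaller medians equal the log2 ratios of UGT2B4, whose fall at 48 h is a lower bound. UGT2B28 was 6.41-fold and UGT2B15 5.69-fold lower at 48 h, while UGT2A3 was 2.54-fold higher at 6 h. Zinc finger genes with ZNF symbols, 372 measured, had medians of -0.09 to -0.01 and lay within the random lists at each time.

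Genes of mitochondrial ribosomal proteins fell at 3 and 6 h. The median log2 ratio over 75 members was -0.28, -0.51, -0.64, -0.38 and -0.35 at 1, 3, 6, 24 and 48 h, with 12 members at least 2-fold lower at 3 h and 18 at 6 h. Besides MRPL34, MRPS26 was 5.26-fold lower at 24 h and MRPL11 5.06-fold at 6 h. Subunits of complex I, 32 measured, had medians of -0.53 at 3 h and -0.60 at 6 h, the former -0.33 without _x_at and _s_at probe sets. Relative to 1 h they were -0.19 and -0.32, below the random lists, and at 24 and 48 h within them. Under quantile normalization and a common median the mitochondrial ribosomal medians at 6 h were -0.64 and -0.59, but without _x_at and _s_at probe sets they were smaller, -0.46 at 6 h and -0.22 at 24 h.

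For this fall at 3 and 6 h, a trend with gene length as the whole cause is argued against. Among random lists matched on expression and length, the family lay at percentile 0 at both times. There was such a trend, with median log2 ratios at 6 h of -0.27 for the shortest genes and -0.03 for the longest. The random median at 6 h was -0.12 matched on expression and -0.21 with length added, against -0.64 for the family. Length may thus account for part of the fall. Length here is genomic span, and transcript length was not tested. A 0 h array that stands apart is argued against by the medians relative to the 1 h array, -0.30 at 3 h and -0.37 at 6 h, both below all random lists. At 24 and 48 h the medians relative to the 1 h array lay within the random lists, at percentiles 9.09 and 17.7. A difference in RNA integrity or labelling may account for the pattern and cannot be told apart from a biological change. The ACTB 3' to 5' ratio was 2.85 times higher at 0 h than at 6 h and shifted along with the family. The GAPDH ratio did so less closely. It was 4.69 at 0 h, 4.29 at 3 h, 3.54 at 6 h and 4.72 at 24 h, where the family median was -0.38. Lower transcript levels during coculture are an equally open hypothesis.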
